A study of Homo sapiens with 3 samples.

How the data were processed

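VDR ChIP-seq was performed in THP-1 cells that were left unstimulated or treated with 10 nM calcitriol for 40 min, after a night in medium with charcoal-stripped serum, per the labels' protocols. A deposited protocol states that chromatin was cross-linked with formaldehyde, sonicated and precipitated with an anti-VDR antibody or non-specific IgG, and that 5 VDR immunoprecipitations were pooled for each sequencing library. Reads were aligned with Bowtie to hg19, per the submitters' processing notes, which give no version. The peak caller, its threshold, the use of the IgG sample as control and any removal of duplicate reads or artefact-prone regions are not given in the sources used here. A threshold that depends on depth or on background would change both the number and the width of peaks.

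The authors deposited 1 peak list per VDR sample, in which the values are genomic positions: chromosome, start and end of each peak, in 3 columns with no header. The deposited lists hold no score, height, fold enrichment or p-value per peak, and no read depth. All starts end in the digit 1 and all ends in 0 or 1, so edges lie on a 10 bp grid. Coordinates are printed as deposited, because the lists do not say whether starts count from 0 or 1, and width is end minus start. Within each list no peaks overlapped, but 194 neighbouring pairs in the unstimulated list and 220 in the calcitriol list were exactly 10 bp apart. The unstimulated list was sorted by position except for 170 rows that follow the sorted rows of their chromosome and begin where the order first breaks; the calcitriol list had none. No columns of other samples were present.

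Samples were grouped by the treatment label, 1 library per condition. Peaks sharing at least 1 bp with a peak of the other list were called shared, and overlapping peaks of the 2 lists were merged into regions. The number of shared peaks was set against 10000 random placements of the calcitriol peaks within their chromosomes, each bounded by the last peak end of either list because chromosome lengths and assembly gaps of hg19 were not used here. Median widths were compared by two-sided permutation tests over peaks (100000 permutations) with bootstrap intervals (2000 draws), and paired widths by sign-flip permutations. Shares have exact Clopper-Pearson 95% intervals and counts exact Poisson 95% intervals. Class by chromosome tables were tested by permuting classes over regions, and isolation also by 10000 permutations of classes within chromosomes. Peaks per Mb used the same chromosome bounds, 3013 Mb in all. Protein-coding genes per chromosome (19974 over the 23 chromosomes) were counted in a RefSeq gene table of GRCh38.p14, of which only each gene's chromosome and type were used. Correlations across chromosomes were tested by 100000 permutations (10000 with whole loci moved and with other peak sets or definitions of sharing). Adjusted p-values are Benjamini-Hochberg values within each family. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

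Designs, tests and alternatives for peak counts, overlap, widths and peaks per chromosome were fixed before the data were examined. The analyses of gene density, classes by chromosome, clusters, isolation, paired widths, joined peaks and row order were added after seeing the data. The functions were tested on simulated lists of the real lengths and widths. With 600, 200 and 0 shared peaks planted, 602, 202 and 3 were found, against random means of 3.5, 3.6 and 3.2. The planted peaks were moved by at most 100 bp, and the simulated peaks were not clustered, unlike the real lists. With no effect planted, 3 of 100 simulations passed 0.05 in the width test on the unstimulated list, 8 of 100 in the class by chromosome test (8 with whole loci moved) and 4 of 100 in the neighbour test. These simulations permuted classes over single regions. They therefore do not show how the version with whole loci moved behaves where neighbours share a class. A shift of 100 bp in median width was found in 43 of 50 simulations.

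Single peaks were to be named by rule as the highest-ranking 8 of each class by the authors' own value or, without one, the 8 widest. Because the only annotation at hand is of another build, peaks were not assigned to genes. The planned positions relative to genes, the 11 gene lists and the motif searches, including the direct repeat of hexamers that VDR is known to bind, were therefore not run, and neither were analyses of peak scores. Alternatives tried were other definitions of sharing, removal of crowded peaks, local moves in place of random placement, joined peaks, removal of out-of-order rows and the wider 50% of each list.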

Results

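Binding sites of the vitamin D receptor (VDR) were mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in THP-1 cells, a human monocytic leukaemia line widely used as a monocyte model. VDR is a nuclear receptor that binds DNA, typically as a heterodimer with a retinoid X receptor, and its natural ligand is calcitriol (1α,25-dihydroxyvitamin D3). The series holds 3 samples: a VDR ChIP from unstimulated cells, a VDR ChIP from cells exposed to 10 nM calcitriol for 40 min, and a ChIP with non-specific IgG from pooled material. Peak lists of the 2 VDR samples were analysed, 1 library per condition, and the IgG sample was not analysed here. Each VDR library combined 5 separate immunoprecipitations before sequencing, so variation between cultures cannot be estimated from it. The lists give the position of each peak with no read count, height or p-value, so the sequencing depth behind each list and the strength of each peak are unknown. Every p-value below is over peaks, regions, placements or chromosomes and compares these 2 libraries, not the conditions. Intervals cover counting error only. Positions are those of the deposited lists, on hg19.

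The first comparison asked how many places in the genome VDR occupied before and after the ligand. The list from calcitriol-treated cells was longer, with 1820 peaks against 1169 in unstimulated cells, which is 1.56 times as many (exact 95% interval 1.45 to 1.68). The calcitriol peaks covered 2.70 Mb and the unstimulated peaks 1.63 Mb. Calcitriol peaks were also somewhat wider, with a median of 1430 bp (quartiles 1090 and 1780 bp) against 1340 bp (1030 and 1710 bp). Both lists reached 23 chromosomes, 1 to 22 and X. Some long enriched stretches were deposited as strings of peaks 10 bp apart, and joining these left 1600 calcitriol and 975 unstimulated sites, a ratio of 1.64.

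The second comparison asked which sites were common to both states. Of the 1169 unstimulated peaks, 732 (62.6%, exact 95% interval 59.8 to 65.4%) shared at least 1 bp with a calcitriol peak, and 437 (37.4%, interval 34.6 to 40.2%) did not. Of the 1820 calcitriol peaks, 717 (39.4%, interval 37.1 to 41.7%) were shared, and 1103 (60.6%, interval 58.3 to 62.9%) were found after calcitriol alone. Merging overlapping peaks of both lists gave 2121 regions, called bound here without a check against the IgG sample. Of these, 437 (20.6%) were unstimulated-only, 581 (27.4%) shared and 1103 (52.0%) calcitriol-only. The lists thus differed in both directions: the treated cells had calcitriol-only regions, and the untreated cells had regions that the treated list lacked.

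The shared fraction was far above random placement. With calcitriol peaks placed at random within their own chromosomes, a mean of 3.32 unstimulated peaks were hit (95% of placements 0 to 8), so the observed 732 was 220.4 times the random value (one-sided permutation p = 0.0001, the smallest that 10000 placements can give). Moving each calcitriol peak by a random 10 to 100 kb, which keeps it in its neighbourhood, gave a mean of 28.8 hits and a ratio of 25.4 with the same p. Neither placement takes account of open chromatin. The ratios therefore do not separate VDR binding from other signal that both libraries of this cell line can share. Shared sites did not always coincide closely. Among 447 pairs in which 1 unstimulated peak overlapped exactly 1 calcitriol peak, the centres lay a median of 235 bp apart, and 118 pairs had centres within 100 bp. With centres within 100 bp required of all peaks, 174 peaks of each list counted as shared. The unstimulated list contains 170 peaks in rows that break its position order, and these were shared less often (29.4%) than the other 999 (68.3%). Without them the unshared fraction of the unstimulated list was 31.7%.

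Shared sites were the wider ones in both lists. In the calcitriol list the median width was 1560 bp for shared and 1359 bp for calcitriol-only peaks, a difference of 201 bp (bootstrap 95% interval 149 to 270 bp, two-sided permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 2e-05 over 2 comparisons). In the unstimulated list the medians were 1390 and 1270 bp, a difference of 120 bp (interval 50 to 180 bp, permutation p = 0.00111, adjusted p = 0.00111). The same sites were wider after calcitriol: over the 447 pairs the mean width was 1513 ± 437 bp (SD over pairs) before and 1717 ± 535 bp after ligand, a mean gain of 204 ± 31.0 bp (SE). The calcitriol peak was the wider one in 277 pairs and the narrower one in 169 (two-sided sign-flip permutation p = 1e-05). After joining adjacent peaks the differences between classes were larger, 391 bp in the calcitriol list and 280 bp in the unstimulated list (permutation p = 0.0001 for both). A wider peak or a joined string has more chance of sharing at least 1 bp. Part of these differences between classes can therefore follow from the definition of sharing, and how large that part is was not tested. With reciprocal overlap of at least 50% required, the difference was 211 bp in the calcitriol list and 219.5 bp in the unstimulated list (permutation p = 0.0001 for both). Under the rule of centres within 100 bp, 174 peaks of each list were shared, and most overlapping peaks counted as unshared. With sharing so defined, the width difference between classes no longer passed the test in either list. It was 50 bp in the calcitriol list (permutation p = 0.292) and 15.0 bp in the unstimulated list (permutation p = 0.746).

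**Figure D1:**
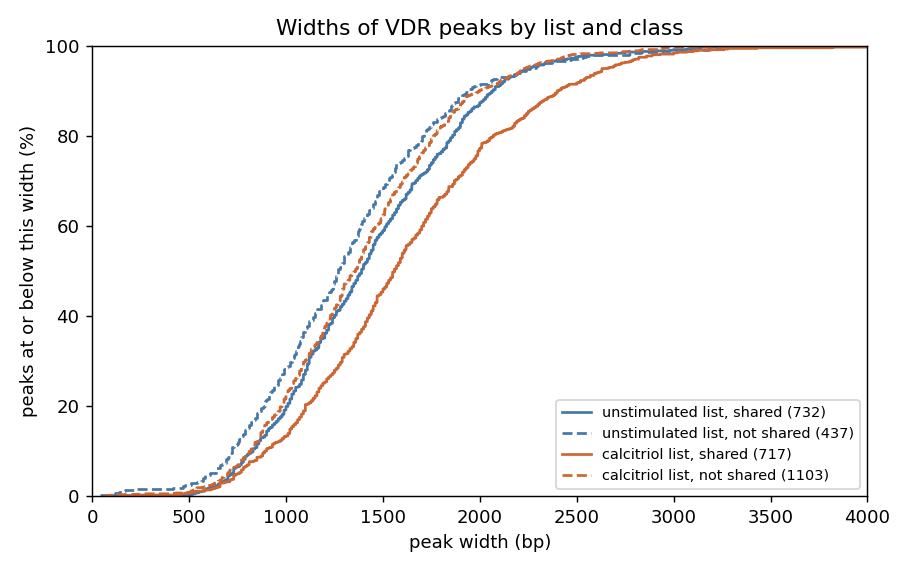
Cumulative distributions of peak width (x axis, bp, drawn up to 4000 bp, which leaves the 2 widest calcitriol peaks of 4130 and 8600 bp off the plot) against the percentage of peaks at or below that width (y axis), for shared (solid) and unshared (dashed) peaks of the unstimulated (blue) and calcitriol (orange) lists. The curve of shared calcitriol peaks lies to the right of the others, with a median of 1560 bp against 1359, 1390 and 1270 bp.

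The widest individual peaks are listed here because the lists hold no other measure per peak. The widest shared peak spanned 8600 bp on chromosome 17 (56382271 to 56390871) and overlapped 5 unstimulated peaks. The next was 4130 bp wide and lay close by on the same chromosome (56404011 to 56408141). Wide shared peaks also lay on chromosome 1 at 244996321 to 245000141 (3820 bp) and at 116517991 to 116521421 (3430 bp), on chromosome 11 at 65543281 to 65546540 (3259 bp) and on chromosome 6 at 135502741 to 135505931 (3190 bp). The widest calcitriol-only peaks lay on chromosome 1 at 111743641 to 111747021 (3380 bp) and at 234858101 to 234861341 (3240 bp), on chromosome 2 at 200319101 to 200322321 (3220 bp), and on chromosome 6 at 106610781 to 106613750 (2969 bp). Of the 8 widest unstimulated-only peaks, 7 lay on chromosome 1 and 6 belong to the out-of-order rows of the list. The widest were at 41325191 to 41329011 (3820 bp), 41155971 to 41159231 (3260 bp) and 144998351 to 145001541 (3190 bp), and these 3 are among the out-of-order rows.

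The chromosomal distribution of the sites was compared next. Chromosome 19, the chromosome with the highest density of protein-coding genes, carried the highest density of VDR peaks in both states, with 2.52 peaks per Mb (exact Poisson 95% interval 2.13 to 2.96) in unstimulated cells and 2.79 (2.38 to 3.25) after calcitriol. Chromosome X carried the lowest, with 0.039 (0.014 to 0.085) and 0.163 (0.105 to 0.240). On chromosomes 16, 22 and 19 the lists were of nearly equal length, with 89 calcitriol against 85 unstimulated peaks, 68 against 64, and 165 against 149. The calcitriol list was longest relative to the unstimulated list on chromosomes X, 10 and 4, with 25 against 6 peaks, 69 against 24, and 59 against 22. It was also more than 2 times as long on chromosomes 2, 3, 12, 15 and 20. The division of regions into the 3 classes differed between chromosomes (chi-square 113.9, permutation p = 1e-05, the smallest that 100000 permutations can give). The p was the same when loci of regions up to 50 kb apart were moved together.

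**Figure D2:**
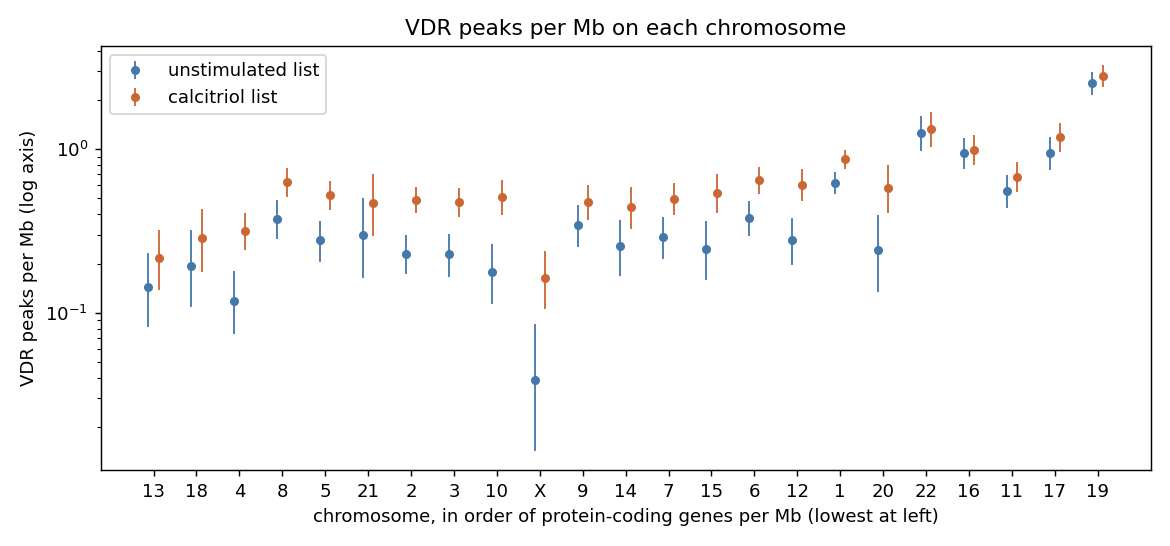
VDR peaks per Mb (y axis, log scale) on each chromosome (x axis, ordered from the lowest to the highest number of protein-coding genes per Mb) in the unstimulated (blue) and calcitriol (orange) lists; bars are exact Poisson 95% intervals of the count. The lists nearly coincide on chromosomes 16, 19 and 22 and lie farthest apart on chromosome X, with 6 and 25 peaks.

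Peak density followed gene density across the 23 chromosomes in both lists, and the calcitriol-only share ran the other way. Spearman's rho with protein-coding genes per Mb was 0.72 for unstimulated peaks per Mb (Pearson's r = 0.92) and 0.80 for calcitriol peaks per Mb (r = 0.94), with permutation p = 0.0002 and 2e-05 for rho (adjusted over 4 relations 0.0004 and 8e-05) and 2e-05 and 1e-05 for r (4e-05 for both adjusted). Calcitriol-only peaks made up 84.0% of the calcitriol list on chromosome X (exact 95% interval 63.9 to 95.5%), 78.0% on chromosome 4 (65.3 to 87.7%), 43.2% on chromosome 17 (33.0 to 53.7%) and 41.2% on chromosome 22 (29.4 to 53.8%). This share fell with gene density (rho = -0.59, permutation p = 0.00354, adjusted p = 0.00472, and r = -0.51, permutation p = 0.00659, adjusted p = 0.00879). The trend had exceptions, and the chromosomes named above are given for their high or low share. Chromosomes 4, 22 and 17 have 4.14, 8.85 and 14.5 genes per Mb, but chromosome X, with the highest share, has 5.52. Chromosome 13, the least gene-dense with 3.03 genes per Mb, had a share of 58.3%. On chromosome 12, with 7.66 genes per Mb, the share was 71.6%. Without chromosomes 19 and 17, the farthest from the median gene density, the relations were r = 0.71 and rho = 0.64 for unstimulated peaks, r = 0.77 and rho = 0.75 for calcitriol peaks, and r = -0.49 (permutation p = 0.0257) and rho = -0.48 (permutation p = 0.0283) for the share. The number of calcitriol-only peaks per Mb was itself highest on chromosome 19 (1.40, against 0.125 on chromosome 13 and 0.137 on chromosome X), so it is the share that fell with gene density. With whole loci of regions up to 50 kb apart moved between chromosomes, the rho of the share kept a permutation p of 0.0037. Restricted to the wider 50% of each list, the relation of the share did not pass the test (rho = -0.36, permutation p = 0.100). Chromosomes differ in more than gene density and are not independent replicates.

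**Figure D3:**
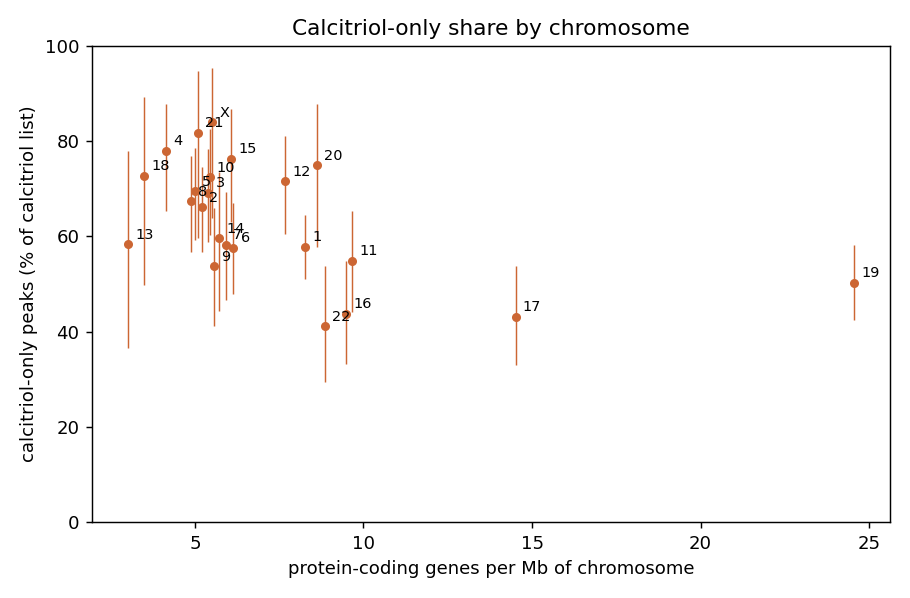
Share of the calcitriol list found after calcitriol alone (y axis, percent, with exact binomial 95% intervals) against protein-coding genes per Mb (x axis) for each of the 23 chromosomes. Chromosomes 16, 17, 19 and 22 lie at 50.3% or lower, and chromosomes X, 21 and 4 at 78.0% or higher.

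Peaks of both lists were more clustered than random placement within chromosomes gives. This placement takes no account of assembly gaps or open chromatin, and the IgG sample was not analysed. The excess therefore does not separate VDR binding from other clustered signal. Windows of 1 Mb with 5 or more peaks numbered 46 in the unstimulated list, where random placement gave a mean of 7.52 and at most 13 in 1000 placements, and they held 36.6% of its peaks. In the calcitriol list 63 such windows (random mean 11.3, at most 18) held 29.0% of peaks. Part of this comes from peaks 10 bp apart, which the placements move separately. After joining these, 33 windows of the unstimulated list (random mean 3.18, at most 9) held 25.9% of its sites, and 48 of the calcitriol list (random mean 6.44, at most 13) held 20.7%. The densest window in both lists was on chromosome 17 from 79000001 to 80000000, with 27 unstimulated and 23 calcitriol peaks. By the sum of both lists it was followed by chromosome 22 from 46000001 to 47000000 with 26 and 22 peaks, and chromosome 19 from 1000001 to 2000000 with 26 and 17 peaks. Among windows with 10 or more peaks, the largest excess after calcitriol was on chromosome 10 from 70000001 to 71000000, with 2 unstimulated and 11 calcitriol peaks, 7 of them calcitriol-only. The first of its calcitriol peaks started at 70820711 and the last ended at 70868400. Chromosome 1 from 155000001 to 156000000 (6 and 14 peaks) and chromosome 19 from 4000001 to 5000000 (7 and 14) came next. These windows were picked after their values were seen. After joining adjacent peaks, the 47 windows were tested against the genome-wide proportion of the lists. None passed after adjustment (exact binomial tests, smallest adjusted p = 0.577). The windows were chosen by deposited peaks, and some held too few sites after joining to pass whatever their division. On chromosome 6 from 68000001, for example, each list held 1 site. The lack of a passing window therefore does not show equal proportions. An unadjusted exact p under 0.05 was found in 4 windows. All 4 held fewer calcitriol sites than that proportion (chromosomes 22 from 46000001, 19 from 1000001, 16 from 4000001 and 1 from 41000001). In the window on chromosome 1, 4 of the 7 unstimulated peaks are out-of-order rows. Without such rows the windows on chromosomes 22 and 19 kept an unadjusted exact p under 0.05 (0.012 and 0.0208), and those on chromosomes 16 and 1 did not (0.062 and 0.673). Removing a piece of a string can split it into separate sites. On chromosome 22 removing 4 peaks raised the unstimulated sites from 13 to 14, and on chromosome 19 removing 5 left them at 17. The p-values of these 2 windows therefore do not show whether they depend on such rows. The chromosome 10 window, with 2 unstimulated and 8 calcitriol sites, had exact p = 0.337, and so few sites leave its excess undecided.

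Calcitriol-only sites were more isolated than the others. With adjacent peaks joined, 15.9% of 1030 calcitriol-only regions (exact 95% interval 13.7 to 18.3%) had another bound region within 10 kb, against 28.5% of 565 shared regions (24.8 to 32.4%) and 22.9% of 389 unstimulated-only regions (18.8 to 27.4%). The median distance to the nearest bound region was 173.2 kb for calcitriol-only, 50.5 kb for shared and 60.8 kb for unstimulated-only regions. Calcitriol-only regions differed from shared (Fisher's exact test, two-sided, p = 5.84e-09, adjusted p = 1.75e-08 over 3 comparisons) and from unstimulated-only regions (exact p = 0.00306, adjusted p = 0.00459). The difference between shared and unstimulated-only regions did not pass the test (exact p = 0.061, adjusted p = 0.061). Because classes also differ between chromosomes, the classes were permuted within chromosomes as well. This alone gave mean differences of 2.73 percentage points between shared and calcitriol-only regions and 2.32 between unstimulated-only and calcitriol-only regions, against 12.6 and 6.96 observed (permutation p = 0.0001 and 0.0406, adjusted p = 0.0003 and 0.0406). Between shared and unstimulated-only regions the observed 5.62 points then passed (permutation p = 0.0318, adjusted p = 0.0406), but only after joining: as deposited the difference was 0.100 points (35.1 against 35.0%, exact p = 1.0, permutation p = 0.685 within chromosomes). Neighbouring regions are not independent, so these p-values are too small.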

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

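With 1 library per condition no replicate could be left out. No paired analysis was possible because each condition has 1 library. Stricter peak thresholds, as well as the alternatives for motifs, gene lists and gene positions, were not run, since the lists hold no scores and no sequence or annotation of hg19 was used. Joining adjacent peaks, removing out-of-order rows, keeping the wider 50% of each list, moving whole loci, a 50 kb distance and leaving out 2 chromosomes were chosen after seeing the data, as were all alternatives for gene density, classes by chromosome, clusters, isolation and neighbours, and leaving out crowded peaks except for the overlap. Of 115 alternative values, 14 could not change, because the alternative leaves that list as it was. Of the others, 74 kept their direction and side of the threshold, stayed within 1.5 times of the count or, for percentages, inside the exact 95% interval of the reported value. The overlap stayed above random placement under all 8 alternatives run (25.4 to 748 times). The unshared percentages of the unstimulated and calcitriol lists were 53.4 and 70.1 with reciprocal overlap of at least 50%, 85.1 and 90.4 with centres within 100 bp (174 shared peaks in each), and 47.4 and 70.8 without crowded peaks (426 shared in each). They were 50.7 and 68.1 in the wider 50% (592 and 911 peaks, 292 and 291 shared). Joining gave 64.4 for the calcitriol list, and dropping out-of-order rows gave 31.7 for the unstimulated list. Fewer peaks or a stricter definition of sharing explain the lower counts by construction. The 31.7 follows from the lower shared fraction of the out-of-order rows (29.4% against 68.3% for rows in order). The 64.4 arises because joining took shared calcitriol peaks from 717 to 570 sites but calcitriol-only ones from 1103 to 1030. The cause of the other moves was not tested. The width difference between classes was 15.0 bp (unstimulated) and 50 bp (calcitriol) with centres within 100 bp and no longer passed. The rank correlation of the calcitriol-only share with gene density was -0.36 in the wider 50% and no longer passed; the cause was not tested. That of the unstimulated-only share, never past the threshold, was -0.16 and turned to 0.11 without crowded peaks, 0.016 after joining and 0.082 in the wider 50%. The number of unstimulated-only regions near a calcitriol-only region, 26.0 below permuted labels, turned to 2.81 above them after joining and was -2.09 in the wider 50%, neither past the threshold; pieces of 1 split site counted as separate regions before joining. With classes permuted within chromosomes, the 5.62 points by which shared regions exceeded unstimulated-only ones in having a neighbour passed the threshold, while with peaks as deposited the difference was 0.100 points and did not pass; the cause was not tested. Read depth is unknown, so how far it limits either list cannot be stated.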

Other observations

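Among the tests of explanations below, only that of shifted edges was fixed before the data were examined; those of splitting, out-of-order rows, libraries per condition, whole loci, unspecific signal and neighbouring sites were chosen after the data were seen, as were the comparisons of adjacent and of out-of-order peaks.

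Several stretches of peaks extended over many kb and were present in both lists. The IgG sample was not analysed, so whether these stretches hold unspecific signal was not tested. In the calcitriol list the longest, on chromosome 22 from 46465471 to 46481571, was a string of 11 adjacent peaks over 16100 bp and overlapped 11 unstimulated peaks. A stretch on chromosome 6 from 68590591 to 68599791 was made of 9 calcitriol peaks and overlapped 8 unstimulated peaks, and one on chromosome 2 from 63278651 to 63286131 of 7 calcitriol peaks overlapped 7. On chromosome 17 the unstimulated stretch from 56381801 to 56394431 held 7 peaks and the calcitriol stretch from 56382271 to 56393961 held 4. Of 32 calcitriol sites with 3 or more adjacent peaks, 30 (93.8%, exact 95% interval 79.2 to 99.2%) overlapped an unstimulated peak, against 31.8% (29.4 to 34.3%) of 1443 single-peak sites (Fisher's exact test, two-sided, p = 5.33e-13). In the unstimulated list 39 of 41 such sites (95.1%, interval 83.5 to 99.4%) overlapped a calcitriol peak, against 56.6% (53.2 to 60.0%) of 848 single-peak sites (exact p = 1.03e-07). Joined sites hold several peaks and so have more chances of a 1 bp overlap than single-peak sites. The tests do not adjust for this, so part of both differences can follow from site length. These stretches were singled out after their values were seen.

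The calcitriol list was longer, yet 37.4% of unstimulated peaks were missing from it. After joining adjacent peaks the ratio of the lists was 1.64, and 39.9% of unstimulated sites were missing. These values argue against splitting of broad sites as the whole cause. With a gap of up to 500 bp allowed 35.2% were still missing, which argues against shifted peak edges as the whole cause. The 170 out-of-order rows are fewer than the 437 missing peaks, so they could not be the whole cause whatever their sharing. Without them 31.7% were missing, a value that therefore adds no test. Variation between ChIP libraries of 1 condition, including peaks near an unknown threshold, cannot be told apart from an effect of calcitriol with 1 library per condition. Replicate libraries of each condition, with reads counted at the same sites, would be needed to decide this.

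The calcitriol-only share was smaller on gene-dense chromosomes. The relation held after joining adjacent peaks (rho = -0.51, permutation p = 0.0125) and without the out-of-order rows (rho = -0.58, permutation p = 0.005), and it was beyond what moving whole loci between chromosomes gave (permutation p = 0.0037), which argues against splitting, row order and neighbouring peaks as the whole cause. In the wider 50% of each list it did not pass the test (rho = -0.36, permutation p = 0.100). Unspecific signal of the unstimulated library on gene-dense chromosomes was examined through the unstimulated-only share, whose rho was -0.16 (permutation p = 0.454). Such signal could lower the calcitriol-only share only where its peaks overlap calcitriol peaks, and those count as shared. The unstimulated-only share therefore cannot decide this, which stays open. Sequence composition and copy number in this aneuploid line were not tested.

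If binding moved from a lost site to a nearby gained one, unstimulated-only regions should lie close to calcitriol-only regions more often than chance. As deposited, 48 of 437 did within 10 kb, below the mean of 74.0 with class labels permuted within chromosomes (permutation p = 0.0002). After joining adjacent peaks 38 of 389 did, against a mean of 35.2 (permutation p = 0.604). The deficit remained within 50 kb (observed minus permuted mean -23.9, permutation p = 0.0064), without crowded peaks (-19.0, permutation p = 0.001) and without the out-of-order rows (-14.3, permutation p = 0.018), and in the wider 50% of each list it was -2.09 (permutation p = 0.688). No alternative gave an excess past the threshold. Because the deficit was lost when pieces of split sites were counted as 1, a move to neighbouring sites was neither seen nor excluded.

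The 170 out-of-order rows of the unstimulated list lay on 22 chromosomes, and 38.2% of them had a neighbouring peak exactly 10 bp away, against 25.6% of rows in order. The out-of-order rows were narrower than the other rows (median 1090 against 1380 bp, two-sided permutation p = 1e-05). They were shared with the calcitriol list in 29.4% of cases (exact 95% interval 22.7 to 36.9%), against 68.3% (65.3 to 71.1%) for rows in order (Fisher's exact test, two-sided, p = 1.87e-21). On chromosome 1, 13 of the 27 such peaks lay between 40 and 46 Mb, and 12 of these 13 were absent from the calcitriol list.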
